A study of Mus musculus with 335 samples.

How the data were processed

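Single cells were sorted by surface markers into plates and their RNA was sequenced by Smart-seq2; each of the 335 cells is 1 sample of the series, identified by its pool and its pair of indices (12 i7 and 8 i5). The 4 groups follow the labels: HSC, Dorsal, Ventral and Mesenchymal, each sequenced as 1 of 4 pools. The labels name no animal or litter, so cells were not used as replicates, and no test, p-value or standard error was computed.

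The deposited table of estimated counts per gene was made by the authors with kallisto 0.43.1 on mouse build GRCm38, per the submitters' processing notes; 8.0% of its values above 0 are under 1 and 0.0399% are whole, and it is not scaled for depth. The deposited log2 table holds log2 of the authors' estimated count divided by a size factor of the cell, plus 1, as the values of the 2 tables show; the size factors average 1.0 and run from 0.098 to 19.6. The annotation, the summing of transcripts to genes, the filters and the method behind the size factors are not stated. Each table has 14109 entries, of which 13448 carry a gene symbol and 661, with 2.96% of all counts, do not. A set of 43 entries without a symbol is scaled in the deposited log2 table by a second factor per cell and holds 0.67% of all counts. The estimated counts of genes with a symbol were used for every value in the report, the log2 table for 1 alternative, and entries without a symbol were left out of totals.

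Counts were summed over the cells of a group and divided by the group's total to give counts per 1000000 (CPM), computed here, with exact Poisson 95% limits on the sum. Limits cover counting error only. Folds are log2 ratios of (CPM + 1) among genes with at least 100 counts over the groups compared. A ratio with 0 counts on 1 side is given as a lower bound against a floor of 3 counts, and a ratio with 1 to 3 counts with its exact limits. For HSC a gene was set against the highest of the 3 other groups if higher and the lowest if lower. Coordinates come from GENCODE M21 on GRCm38, where 13213 symbols were found and 235 were not. Cells with odd and with even i7 index were also summed separately, which shows the range within a pool and not between embryos. Summed counts weight deep cells more, and the deepest Ventral cell (Ventral 41) held 18.5% of its pool, so values without it were computed for the list members and named genes. The median log2 fold over all measured genes was 0.14 for Dorsal against Ventral and 0.09 for Ventral against Mesenchymal, and with cells weighted equally -0.02 and 0.22.

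Before the data were examined, 25 gene lists, 17 sets of cell type markers, the genes for shares of positive cells and the rule for named genes were fixed. Per comparison and direction the rule takes the 12 genes with the largest fold that have at least 5 counts in 25% of the cells of the higher group and differ at least 2-fold the same way with cells weighted equally and in the odd-index and even-index cells. Sort genes, mitochondrially encoded genes, pseudogenes and unnamed loci are left out. From each list the 2 to 4 members with the largest fold may be named; any other gene was chosen after its values were seen, as were Postn, Ednrb, Foxc2, Nr2f1, Wnt5a, Cdc6 and Ccne1 for Dorsal against Ventral, Igf2, Ptn and Bmp4 for Ventral against Mesenchymal, Myb and Angpt1 for HSC, and the genes described across clusters. A list is described by its members at least 2-fold higher or lower and by the percentile of its median fold among 10000 random lists matched in 20 bins of expression, which is no test. Genes on more than 1 list count in each.

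Shares of positive cells used at least 5 counts after each cell was thinned at random to 310000 counts, the 10th percentile of totals rounded down to 10000; 1 HSC, 1 Dorsal, 9 Ventral and 19 Mesenchymal cells lay below and were left out. Limits are exact Clopper-Pearson limits; beside a share of 0 the share that 3 cells would make is also given. Chga, Neurod1, Pou4f1 and Hba-x were planned and are not analysed here, since no entry carries their symbol, and some genes that the lists or the rule name are not reported here. Dorsal and Ventral cells were clustered on log2(CPM/10 + 1) of the 2000 most variable genes, 20 principal components and Ward linkage into 6 clusters; 111 genes of 7 lists were kept out so that they could be described across clusters. Of the 2000 genes, 576 differed at least 2-fold between the pools, so the clustering was repeated without these. Clusters were named by the fixed marker sets. No doublet caller was run, since cells were sorted singly into wells.

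Dock10 and Cep97 held 6.98% and 2.2% of all counts, and Dock10 and Pecam1 had at least 5 counts in 335 of 335 cells, so Pecam1 was not used to identify endothelial cells and an alternative left Dock10 and Cep97 out of the totals. The largest correlation between cells of a group was 0.704 in HSC, 0.738 in Dorsal, 0.723 in Ventral and 0.657 in Mesenchymal, so no cell was a copy of another.

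Alternatives fixed beforehand were equal weight of cells, median-of-ratios size factors, totals without mitochondrially encoded genes, pseudocounts of 0.1 and 5 CPM, no count filter, cells with at least 50000 counts, 2000 genes and under 15% mitochondrial counts, removal of the 5% deepest cells, odd-index or even-index cells, the deposited log2 values, other count limits for shares, and other clusterings, among them Leiden with 15 neighbours at resolution 1. Alternatives added after seeing the data left out the deepest Ventral cell, that cell and the Ventral wells that share an i7 or i5 index with it, Dock10 and Cep97, the cells of cluster 2 or the cells of cluster 6. Cluster 2 includes the deepest Ventral cell, so leaving out its cells also left out that cell. The procedure was tested on simulated data: among simulated log2 folds of 2 and -2, 96.0% and 94.0% came out at least 2-fold for Dorsal against Ventral, 88.0% and 90.0% for Ventral against Mesenchymal, and 92.0% and 96.0% for HSC, while 3.64%, 5.57% and 1.16% of unchanged genes did, and 6 simulated clusters were recovered with an adjusted Rand index of 1.0. In the simulation genes varied independently between cells around 1 mean profile, and simulated clusters differed by strongly raised genes. Subpopulations within a pool and cross-talk between wells were not simulated, so these rates do not cover them. For HSC the other groups shared 1 simulated profile, so the choice of the highest or lowest group was not tested. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.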

Results

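Messenger RNA of 335 single cells from the aorta-gonad-mesonephros (AGM) region of wild-type mouse embryos at stage E11.5 was measured by full-length single-cell RNA sequencing. The AGM is a site where haematopoietic stem cells (HSCs) arise. The cells fell into 4 sorted groups: 65 EPCR+CD45+ cells that include the HSCs (HSC), 93 Ngfr+Pdgfrb- cells from the dorsal side of the aorta (Dorsal), 89 Ngfr+Pdgfrb- cells from its ventral side (Ventral), and 88 Pdgfrb+Ngfr- cells, also ventral, that include subaortic mesenchyme (Mesenchymal). Ngfr is a receptor carried by neural crest-derived cells, and Pdgfrb a receptor of mesenchymal cells and pericytes. Each group was 1 sequencing pool and the labels name no animal, so each group counted as 1 sample. Values below compare 4 pools, and a difference between pools cannot be told from a difference between their libraries.

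Summed estimated counts were 82522446 for HSC, 108417666 for Dorsal, 110607117 for Ventral and 68567503 for Mesenchymal. The median cell held 943850 counts and 7342 detected genes in HSC, 1033986 and 8559 in Dorsal, 574804 and 7801 in Ventral, and 505996 and 6697 in Mesenchymal. Totals per cell ran from 276624 to 7093714 in HSC, from 279653 to 3861630 in Dorsal, from 149631 to 20481212 in Ventral and from 127071 to 6200880 in Mesenchymal. The deepest cell held 8.6%, 3.6%, 18.5% and 9.0% of its pool's counts in the same order. Mitochondrially encoded genes took a median of 4.36%, 5.09%, 5.47% and 5.34% of a cell's counts.

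**Figure D1:**
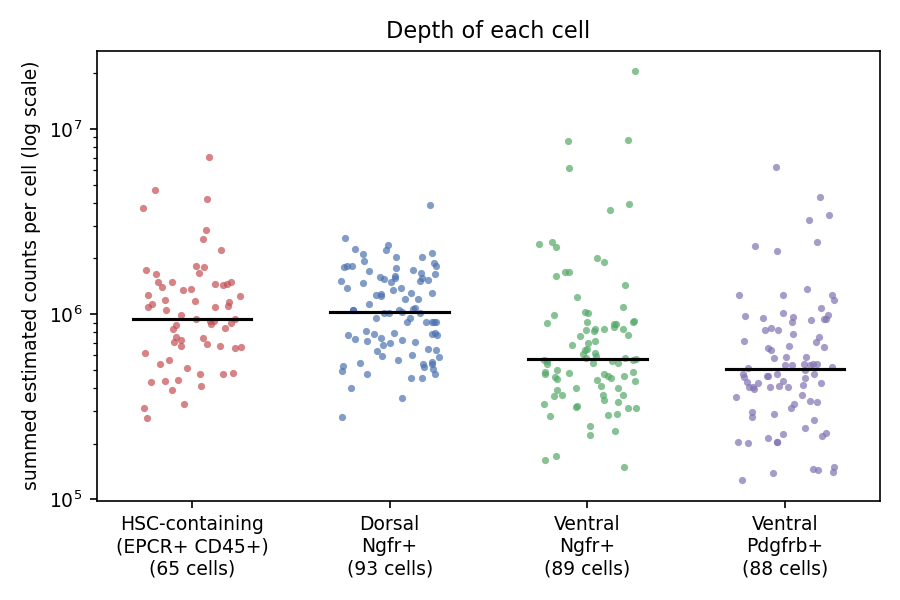
Total estimated count of each cell in the 4 sorted groups, with the median of each group.

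Dorsal and Ventral Ngfr+ cells were compared to ask how Ngfr+ cells, a fraction rich in neural crest derivatives, differ between the 2 sides of the aorta. The Dorsal pool held more RNA of glial and Schwann cell precursor genes. Sox10 (chromosome 15, 79154908 to 79165240, minus strand, GRCm38), the transcription factor that maintains neural crest and glial identity, stood at 316 counts per 1000000 (CPM; 95% limits 312 to 319) in Dorsal and 78.6 CPM (77 to 80.3) in Ventral. Its log2 fold on the (CPM + 1) scale, used for every log2 fold below, was 1.99. Mbp (chromosome 18, 82475146 to 82585637, plus strand), which encodes a myelin protein, stood at 29.2 CPM (28.2 to 30.3) in Dorsal and 3.47 CPM in Ventral, a log2 fold of 2.76. Mbp was not confined to Ngfr+ cells: it stood at 9.71 CPM in HSC. At least 5 Mbp counts were found in 29.2% of HSC and 25.8% of Dorsal cells, unthinned. The limits cover counting error only and not the difference between embryos or pools.

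Of 18 measured neural crest and glial genes, 12 were at least 2-fold higher in Dorsal and 0 lower, and the list's median fold lay at percentile 100 of 10000 expression-matched random lists. Besides Sox10 these included Gfra3 (116 against 23.4 CPM), a receptor subunit for artemin, Foxd3 (23.8 against 5.47 CPM) and Postn (588 against 160 CPM). Without the deepest Ventral cell the number was 7. Without the cells of the mostly Ventral cluster 2, which include that deepest cell, it was 6. In the odd-index and even-index cells it was 6 and 16. Receptors for neurotrophic and guidance signals, 17 measured, were at least 2-fold higher in Dorsal for 6 and lower for 1 (percentile 100). They included Dcc (log2 fold 1.66), Gfra4 (1.60), Nrp1 (1.19) and Ednrb (1.13, and 0.84 without the deepest Ventral cell), and the number higher was 4 without that cell, 4 in odd-index and 12 in even-index cells.

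The genes that the naming rule placed highest in Dorsal included Afap1l2 (log2 fold 3.53), Dct (3.49), Plscr4 (3.09), Art3 (3.02), Plekhb1 (2.98), Gpr37 (2.94), Slc35f1 (2.83), Hbegf (2.77), Mbp (2.76) and Egfl8 (2.72). Dct encodes an enzyme of melanin synthesis and Gpr37 a receptor of myelinating glia. Afap1l2 stood at 68.9 CPM in Dorsal and 5.05 CPM in Ventral, Dct at 25.2 and 1.34 CPM, and Egfl8 at 117 and 16.9 CPM. The rule asks for at least 2-fold in the odd-index and in the even-index cells, and the lowest such value was 2.12 for Egfl8.

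Mesenchymal transcription factors were higher in the Ventral Ngfr+ pool: of 18 measured, 9 were at least 2-fold lower in Dorsal and 0 higher (percentile 0.0). Meox1 (1.06 CPM in Dorsal, 26 in Ventral), a factor of paraxial mesoderm, and Foxc2 (0.68 and 19.5 CPM) had log2 folds of -3.71 and -3.61, and -4.0 and -3.89 without the deepest Ventral cell. Prrx1 (3.50 and 114 CPM) and Tbx18 (0.36 and 21.6 CPM) had log2 folds of -4.68 and -4.05, which were -1.57 and -1.85 without that cell, and -0.93 and -2.07 without it and the wells that share an index with it. Nr2f1 changed sign without it, from -1.53 to 0.74. Osr2 had 0 counts in Dorsal and 3599 in Ventral, at least 1176-fold higher in Ventral against a floor of 3 counts over the Dorsal pool, and at least 70.2-fold higher without the deepest cell. Without the cells of cluster 2, 3 of the list were at least 2-fold lower in Dorsal and 2 higher.

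Signals that act on HSCs in their niche were also higher in Ventral for 7 of 24 measured ligands and higher in Dorsal for 2 (percentile 0.1). Cxcl12 (chromosome 6, 117168535 to 117181367, plus strand), the chemokine that retains HSCs in their niche, stood at 5.57 CPM in Dorsal and 153 CPM in Ventral, a log2 fold of -4.55, and -2.07 without the deepest Ventral cell. Ptn, a secreted growth factor, stood at 6.43 and 169 CPM (-4.52, and -3.13 without that cell), and Bmp4 at 0.07 and 52.1 CPM (-5.63, and -2.84 without it). Il1b, an inflammatory cytokine, stood at 1.52 and 52.7 CPM (-4.41), but at -0.49 over the cells of clusters 1, 3, 4 and 5, which leave out the macrophage-like cluster 6. Wnt5a (log2 fold 1.79) and Jag1 (1.31) were the ligands at least 2-fold higher in Dorsal. Without the cells of cluster 2, 5 ligands were at least 2-fold higher in Ventral and 4 in Dorsal, and without those of cluster 6, 5 and 3.

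The 12 genes that the naming rule placed lowest in Dorsal were Adh1, Ptn, Fgfr2 (log2 fold -4.38), St3gal6 (-3.56), Unc5c (-3.28), Glb1l2 (-3.11), Zfp202 (-3.04), Chchd10 (-2.90), Asb4 (-2.62), Cdh11 (-2.55), Cmss1 (-2.41) and Ttk (-2.40). Adh1 (chromosome 3, 138260991 to 138290698, plus strand), an enzyme that oxidizes retinol, had 0 counts in Dorsal and 476 CPM in Ventral, with 50763 of its 52600 Ventral counts in the deepest cell. It was at least 17186-fold higher in Ventral against a floor of 3 counts. At least 5 counts were found in that cell, in 17 of the 17 wells that share an index with it and in 7 of 71 others, so cross-talk between indices could have made much of the 28.1% share by which the rule placed it. Without all cells that share an index with the deepest cell, Adh1 was at least 250-fold higher, at 6.93 CPM, with 316 of the 513 counts in 1 cell. Without that cell the log2 fold of Fgfr2 was -2.90, of St3gal6 -2.25, of Zfp202 -0.76, of Chchd10 -1.23, of Asb4 -1.61 and of Cmss1 -1.39, while Unc5c (-2.87), Glb1l2 (-3.40), Cdh11 (-2.58) and Ttk (-2.69) moved less.

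Of 37 measured cell cycle genes, 11 were at least 2-fold lower in Dorsal and 2, Cdc6 and Ccne1, at least 2-fold higher (percentile 0.0; Ccne1 1.08, and 0.79 without the deepest Ventral cell). Mki67, a marker of cycling cells, stood at 73.7 CPM in Dorsal and 175 CPM in Ventral (log2 fold -1.23), Ccnb2 at 79.5 and 285 CPM (-1.83), Ube2c at 122 and 430 CPM (-1.81) and Cdc20 at 75.7 and 268 CPM (-1.81). The number lower was 18 in odd-index and 3 in even-index cells, 4 without the 5% of cells with the highest totals, and 17 without the deepest Ventral cell. None of 5 measured CDK inhibitors differed 2-fold (percentile 35.4). Cdkn1c (chromosome 7, 143458339 to 143461050, minus strand), an imprinted CDK inhibitor, stood at 3394 CPM in Dorsal and 2256 CPM in Ventral, a log2 fold of 0.59.

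**Figure D2:**
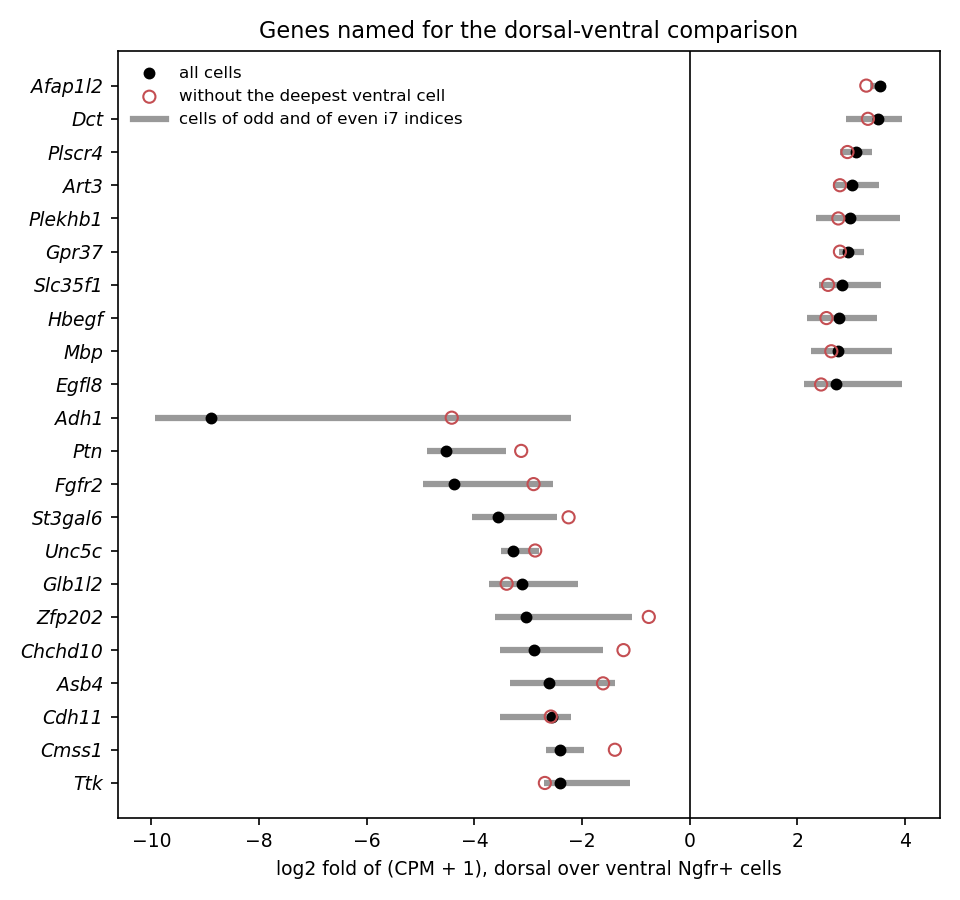
Log2 fold of named genes, Dorsal over Ventral Ngfr+ cells, with and without the deepest Ventral cell and in odd-index and even-index cells.

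Genes of catecholamine synthesis, storage and uptake, 10 measured, stayed within 2-fold between the sides (percentile 96.2). Dbh (chromosome 2, 27165233 to 27183200, plus strand), which makes noradrenaline, stood at 356 CPM (353 to 360) in Dorsal and 279 CPM (276 to 282) in Ventral, a log2 fold of 0.35. Th (chromosome 7, 142892752 to 142931128, minus strand), the rate-limiting enzyme of the pathway, stood at 33.3 CPM (32.3 to 34.4) and 29.8 CPM (28.8 to 30.8), a log2 fold of 0.16. Both varied widely within the pools: the odd-index and even-index cells gave -0.40 and 1.90 for Dbh and -1.23 and 2.36 for Th, Th stood at -0.13 without the deepest Ventral cell, and 4 of the 10 genes were within 2-fold in the even-index cells. Of 14 sympathoadrenal transcription factors, 0 were at least 2-fold higher and 2 lower in Dorsal (percentile 37.1), namely Tbx20 (49.2 against 142 CPM) and Hand1 (4.27 against 12.3 CPM), with 1 higher and 6 lower in odd-index cells and 5 and 0 in even-index cells. Of 19 pan-neuronal genes, 0 were higher and 1, Snap25 (14.7 against 33.9 CPM), lower (percentile 43.1). In even-index cells 14 were higher, in odd-index cells 6 were lower, and without the deepest Ventral cell 3 were lower.

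Of 31 measured Hox genes, which pattern the body axis, 3 were at least 2-fold higher and 6 lower in Dorsal (percentile 37.5), with Hoxd11 (log2 fold -2.82), Hoxb1 (-2.31), Hoxd10 (-2.16) and Hoxc10 (-2.12) the lowest. The odd-index cells gave 1 higher and 9 lower and the even-index cells 8 and 6, and Hoxb1 stood at 0.31 over the cells of clusters 1, 3, 4 and 5. Among 23 imprinted genes 1 was higher and 4 lower (percentile 91): Asb4 and Plagl1 (46.1 against 159 CPM, log2 fold -1.77) were lower in Dorsal; without the deepest Ventral cell Plagl1 stood at -0.24 and 2 genes were lower, without the cells of cluster 2 the list gave 0 higher and 1 lower, and in even-index cells 8 and 4. Extracellular matrix genes, 28 measured, were higher for 6 and lower for 3 (percentile 99.2), and higher for 12 without the cells of cluster 2, with Lama4 at 131 against 41.3 CPM, and Tnc at a log2 fold of -3.32 that was -0.42 without the deepest Ventral cell. Smooth muscle genes, 16 measured, were higher for 2 and lower for 4 (percentile 54.2), among them Acta2 (log2 fold -2.27) and Mcam (1.75), and lower for 0 without the cells of cluster 2.

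Signalling lists held single genes that differed. Wnt response genes, 13 measured, were at least 2-fold higher in Dorsal for 3, with Nkd2 (74 against 18.8 CPM) and Sfrp1 (190 against 65.8 CPM), and lower for 3, with Rspo3 (log2 fold -2.71; percentile 22.8). Notch response genes, 15 measured, were higher in Dorsal for 3, namely Hes1 (89.2 against 35.2 CPM), Jag1 (27 against 10.3 CPM) and Heyl (69.4 against 31.6 CPM), and lower for 0 (percentile 94.9); the number higher was 2 without the deepest Ventral cell, where Heyl stood at 0.82, 0 without the cells of cluster 2 and 7 in even-index cells. Genes of the BMP and TGF-beta response, 14 measured, were higher for 1, Id4 (log2 fold 1.67), and lower for 4, with Bmper (-2.33; percentile 10.2). Hedgehog genes, 9 measured, were higher for 1, Smo (1.03, and 0.74 without the deepest Ventral cell), and lower for 2, with Boc (-1.32; percentile 3.5).

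Haematopoietic genes were present in the Ngfr+ pools, which held a macrophage-like cluster, cluster 6, but not all of them belonged to it. Kit was positive in 1 of 15 thinned cells of cluster 6 and in 20 of 26 of cluster 4. Itga4 was among the genes that define cluster 1. Of 28 HSC receptors 4 were higher and 2 lower in Dorsal (percentile 94.1), with Itga4 at 348 against 93.4 CPM and Kit at 27.6 against 62.6 CPM. Of 24 haematopoietic transcription factors 2 were higher and 3 lower (percentile 8.0), with Ikzf2 at 10.9 against 0.89 CPM. The list gave 2 and 7 without the cells of cluster 6, and 1 and 5 without the deepest Ventral cell. It gave 5 and 5 in odd-index and 4 and 6 in even-index cells. Sensory neuron genes, 4 measured, were higher for 1, Shox2 (percentile 84), and adrenergic and dopamine receptors, 3 measured, for 0 and lower for 0 (percentile 20.6). Dissociation stress genes, 16 measured, were higher for 2 and lower for 2 (percentile 61.6; 4 and 1 without the cells of cluster 6), with Jun at 300.1 against 91.6 CPM and Atf3 at 7.71 against 45.3 CPM, and glycolysis genes, 18 measured, for 1 and 1 (percentile 53.5), Pfkp and Eno2. Of 4 sex-linked genes Eif2s3y was lower in Dorsal (log2 fold -2.22, and 0.80 without the deepest Ventral cell; percentile 18.4), and of the 4 sort genes Ngfr was higher (281 against 90.9 CPM; percentile 56.4).

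Ventral Ngfr+ cells and Ventral Pdgfrb+ mesenchymal cells were compared to ask what separates the Ngfr+ cells below the aorta from the mesenchyme beside them. Dbh stood at 279 CPM (276 to 282) in Ventral with 0 counts in Mesenchymal, at least 6376-fold higher against a floor of 3 counts. Th stood at 29.8 and 0.57 CPM and Cyb561 at 43.3 and 0.03 CPM. Of 10 measured catecholamine genes 6 were at least 2-fold higher in Ventral and 0 lower, of 14 sympathoadrenal transcription factors 10 and 0, of 18 neural crest and glial genes 12 and 0, and of 19 pan-neuronal genes 15 and 2, each at percentile 100. Tlx2 and Erbb3 had 0 counts in Mesenchymal and were at least 3306-fold and 1925-fold higher in Ventral, and the neuronal genes Tubb3 (353 against 6.01 CPM) and Elavl4 (155 against 2.03 CPM) were higher too.

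The mesenchymal pool held the contractile and matrix programme. Of 19 smooth muscle genes 17 were at least 2-fold higher in Mesenchymal and 0 in Ventral (percentile 0.0), and of 28 extracellular matrix genes 19 and 1 (percentile 0.0). Acta2 (chromosome 19, 34241090 to 34255590, minus strand), the actin of smooth muscle, stood at 1578 CPM in Mesenchymal and 11.9 CPM in Ventral, a log2 fold of -6.94, and Rgs5, a pericyte gene, at 368 and 2.86 CPM. Fbln5 (chromosome 12, 101746565 to 101819055, minus strand), which assembles elastic fibres, stood at 137 and 0.09 CPM, a ratio of 1512 (822 to 3154). Col1a1, a fibrillar collagen, stood at 571 and 12.6 CPM. Of 20 mesenchymal transcription factors 10 were higher in Mesenchymal and 3 in Ventral (percentile 0.0), and 17 were higher in Mesenchymal without the cells of cluster 2, with Twist2 (log2 fold -4.55) and Snai2 (-4.36) higher in Mesenchymal, and Osr2 at 4.0 in the other direction but 0.49 without the deepest Ventral cell.

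Of 23 HSC niche ligands 10 were at least 2-fold higher in Mesenchymal and 6 in the Ventral Ngfr+ pool (percentile 0.0); 3 were higher in Ventral without the cells of the macrophage-like cluster 6. Cxcl12 stood at 1238 CPM in Mesenchymal and 153 CPM in Ventral, Igf2 at 1098 and 146 CPM, Ptn at 985 and 169 CPM, and Angpt1, a ligand of the Tek receptor, at 64.2 and 2.93 CPM. Without the deepest Ventral cell the log2 folds of Cxcl12, Ptn and Bmp4 were -5.48, -3.92 and -4.25, against -3.01, -2.54 and -1.46 with it. Il1b, highest in cluster 6, had 0 counts in Mesenchymal and 52.7 CPM in Ventral. Neurotrophic receptors, 17 measured, were higher in Ventral for 6, with Ret (log2 fold 5.14), and lower for 6, with Ntrk2 at 1.71 against 161 CPM (percentile 31.4). Of 16 listed sensory neuron genes only 3 were measured, too few to describe sensory neurons. These 3 were lower in Ventral, with Ntrk3 (-3.12, list percentile 0.0).

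Cdkn1c stood at 2256 CPM in Ventral and 625 CPM in Mesenchymal, and of 5 CDK inhibitors 2 were higher in Ventral and 0 lower. Of 37 cell cycle genes 2 were higher and 1 lower in Ventral (percentile 95), with Ccnd1 at 397 against 61.2 CPM. In odd-index cells 14 were higher, in even-index cells 8 were lower, and without the deepest Ventral cell 6 were higher and 0 lower. Of 25 haematopoietic transcription factors 11 were higher and 7 lower (percentile 98.9), and 5 were higher without the cells of the macrophage-like cluster 6. Spi1, a myeloid factor, stood at 32.8 CPM in Ventral with 0 counts in Mesenchymal, and Mecom at 0.80 and 80.3 CPM. Of 27 HSC receptors 7 were higher and 4 lower (percentile 28.2), with Csf1r at 148 and 1.56 CPM, and 3 were higher without the cells of cluster 6. Glycolysis genes, 18 measured, were higher for 5 and lower for 0 (percentile 99.8), with Ldha at 1189 and 470 CPM, and higher for 9 in odd-index and 2 in even-index cells.

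Imprinted genes, 23 measured, were higher in Ventral for 2 and in Mesenchymal for 6 (percentile 0.1), with Peg3 at 493 and 2026 CPM; the odd-index cells gave 6 and 8 and the even-index cells 1 and 9. Hox genes, 31 measured, were higher in Ventral for 2 and in Mesenchymal for 10 (percentile 12.8). Without the deepest Ventral cell the Hox counts were 4 and 7. Wnt response genes, 13 measured, were higher in Ventral for 3 and in Mesenchymal for 6 (percentile 0.5), with Dkk1 (log2 fold -3.76). Notch response genes, 14 measured, were higher in Ventral for 5, with Mfng (4.99) and Dll3 (4.16), and lower for 6. Hedgehog genes, 9 measured, were higher for 2 and lower for 2, with Gli2 (-2.62), BMP and TGF-beta response genes, 14 measured, for 2 and 2, with Msx1 (3.39), and stress genes, 16 measured, for 2 and 1, with Zfp36 (2.87), but for 1 and 5 without the cells of cluster 6. Adrenergic and dopamine receptors, 4 measured, were higher in Ventral for 1 and lower for 1, Adra1d (percentile 40.5), sex-linked genes, 4 measured, for 2 and 0 (1 and 0 without the deepest Ventral cell, where Eif2s3y stood at 0.28 against 3.30 with it), and the sort genes for 2, Ptprc and Ngfr, and 1, Pdgfrb.

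The genes placed highest in Ventral against Mesenchymal included Dbh (log2 fold 8.13), Tlx2 (7.19), Nell2 (6.74), Cck (6.71), Fcer1g (6.60), Erbb3 (6.41), Sox10 (6.16), Laptm5 (5.98), Csf1r (5.86), Coro1a (5.76) and Akr1cl (5.72). Fcer1g, Laptm5, Csf1r and Coro1a are genes of macrophages and other leukocytes, and Akr1cl stood at 2.53 without the deepest Ventral cell. The macrophage-like cluster 6 held 11.2% of Ventral cells. At least 5 counts were found in 33.7% of Ventral cells for Laptm5, 31.5% for Csf1r and 29.2% for Coro1a, and in 17.5% of thinned cells for Csf1r. Cross-talk between indices could have made much of the shares by which the rule placed Laptm5, Csf1r and Coro1a. Fcer1g had at least 5 counts in 74.2% of Ventral cells. Of thinned Ngfr+ cells outside cluster 6, 43.3% were positive for Fcer1g and 1.9% for C1qb. Their CPM in Ventral was 110.5 and 174.91, which argues against cross-talk from cluster 6 as the main source of the Fcer1g share. The 12 placed lowest were Fbln5, Acta2, Iigp1 (-6.88), Ddr2 (-6.82), Actc1 (-6.77), Cyp1b1 (-6.67), Rgs5 (-6.58), Wisp1 (-6.03), Ntrk2 (-5.90), Cnn1 (-5.85), Cd248 (-5.63) and Actg2 (-5.54). Cyp1b1 had 1 count in Ventral and 102 CPM in Mesenchymal, a ratio of 11269 with limits of 2022 and 445173.

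HSC-containing cells were set against all 3 other groups to ask what marks the stem and progenitor pool within its surroundings; a gene counted as higher when it exceeded the highest of the 3, and as lower when it lay below the lowest. Of 27 haematopoietic transcription factors 17 were at least 2-fold higher in HSC and 0 lower (percentile 100). Gfi1 (chromosome 5, 107716657 to 107726036, minus strand), a transcriptional repressor that acts in HSC emergence and maintenance, stood at 42.6 CPM with 0 counts in each of Dorsal, Ventral and Mesenchymal. Hlf (127 CPM, log2 fold 5.47), Lmo2 (206 CPM, 5.23), Myb (197 CPM, 4.75) and Runx1 (193 CPM, 3.49) were higher in HSC as well. Of 29 HSC receptors 8 were higher and 3 lower (percentile 56.4), with Tek (133 CPM, 6.06), Flt3 (3.77) and Kit (497 CPM, 2.46). Of 24 niche ligands 4 were higher, with Fgf2 (2.13) and Angpt1 (231 CPM, 1.83), and 7 lower, with Tgfb2 (-5.83).

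The 12 genes placed highest in HSC were Mpo (log2 fold 7.75), Mmrn1 (7.52), Gimap6 (6.53), Car2 (6.48), Myct1 (6.34), Pdzk1ip1 (6.30), Tspan32 (6.14), Hbb-bt (6.14), Tek (6.06), Ptprcap (5.90), Cd34 (5.77) and Olfr65 (5.76). Mpo (chromosome 11, 87793581 to 87804413, plus strand), the peroxidase of myeloid granules, stood at 297 CPM in HSC and at 0.08, 0.22 and 0.38 CPM in Dorsal, Ventral and Mesenchymal. Mmrn1 had 184 CPM in HSC, 1 count in Dorsal and 0 in the other groups, a ratio of 19918 (3574 to 786788) over Dorsal and at least 6774-fold and 4199-fold over Ventral and Mesenchymal. The 12 placed lowest were Sox11 (-6.63), Col1a2 (-6.48), Col3a1 (-6.41), Vcan (-6.36), Cdh2 (-6.36), Parm1 (-6.32), Crabp2 (-6.13), Gpc6 (-5.98), Col5a1 (-5.97), Ncam1 (-5.89), Nr2f2 (-5.87) and Tgfb2. Sox11 (chromosome 12, 27334264 to 27342574, minus strand) stood at 2.71 CPM in HSC and at 367, 380 and 485 CPM in Dorsal, Ventral and Mesenchymal.

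Of 31 Hox genes 19 were at least 2-fold lower in HSC than in each of the 3 other groups and 0 higher (percentile 0.0), with Hoxc9 (log2 fold -3.24) the lowest; the number lower was 4 with a pseudocount of 5 CPM and 8 with the deposited log2 values. Of 28 extracellular matrix genes 18 were lower and 0 higher. Imprinted genes, 23 measured, were lower for 14 and higher for 1, with Nnat (-5.8), Mest (-5.74) and Cdkn1c (270 CPM, -1.21). Lower and higher members numbered 12 and 0 of 19 pan-neuronal genes, 10 and 0 of 17 neurotrophic receptors, 6 and 0 of 14 sympathoadrenal factors, 6 and 0 of 18 neural crest genes, 9 and 0 of 19 smooth muscle genes, and 8 and 0 of 20 mesenchymal transcription factors. They numbered 8 and 0 of 14 BMP and TGF-beta response genes (Id3, -4.22), 6 and 0 of 13 Wnt response genes (Sfrp1, -5.50), 5 and 0 of 9 hedgehog genes (Gas1, -5.76), 3 and 2 of 15 Notch response genes (Heyl, -5.03), and 6 and 2 of 16 stress genes (Fos, -3.92). They numbered 1 and 1 of 18 glycolysis genes (Eno1, -1.83), 1 and 0 of 37 cell cycle genes (Ccnd1, -3.11), and 1 and 0 of 5 CDK inhibitors.

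Catecholamine genes, 10 measured, were lower in HSC for 1, Ddc (log2 fold -2.88), and higher for 1, Slc18a2 (176 CPM, 2.22), which encodes the vesicular monoamine transporter. None of 4 adrenergic and dopamine receptors or 5 sensory neuron genes lay 2-fold outside the range of the other groups. Of the 4 sex-linked genes 3 were higher in HSC, with Kdm5d (2.51), and of the sort genes Procr and Ptprc were higher, Ngfr and Pdgfrb lower.

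The share of cells with at least 5 counts of a gene was taken after each cell was thinned to 310000 counts, which kept 64 HSC, 92 Dorsal, 80 Ventral and 69 Mesenchymal cells. Sox10 was positive in 85.9% of Dorsal cells (77 to 92.3) and 43.8% of Ventral cells (32.7 to 55.3), Erbb3 in 70.7% and 40%, Foxd3 in 35.9% (26.1 to 46.5) and 12.5% (6.2 to 21.8), and Ngfr in 80.4% and 53.8%. Dbh was positive in 45.7% (35.2 to 56.4) and 37.5% (26.9 to 49), Th in 30.4% (21.3 to 40.9) and 18.8% (10.9 to 29), Gata3 in 59.8% and 51.2%, Gata2 in 25% and 33.8%, and Hand2 in 29.3% and 38.8%. Mki67 was positive in 33.7% (24.2 to 44.3) and 50% (38.6 to 61.4), Top2a in 60.9% and 66.2%, Kit in 23.9% and 47.5%, and Cdkn1c in 100% and 97.5%. Unthinned shares were 94.6% and 50.6% for Sox10, 58.1% and 15.7% for Foxd3, 86% and 59.6% for Dbh, 39.8% and 19.1% for Th, and 35.5% and 58.4% for Mki67.

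**Figure D3:**
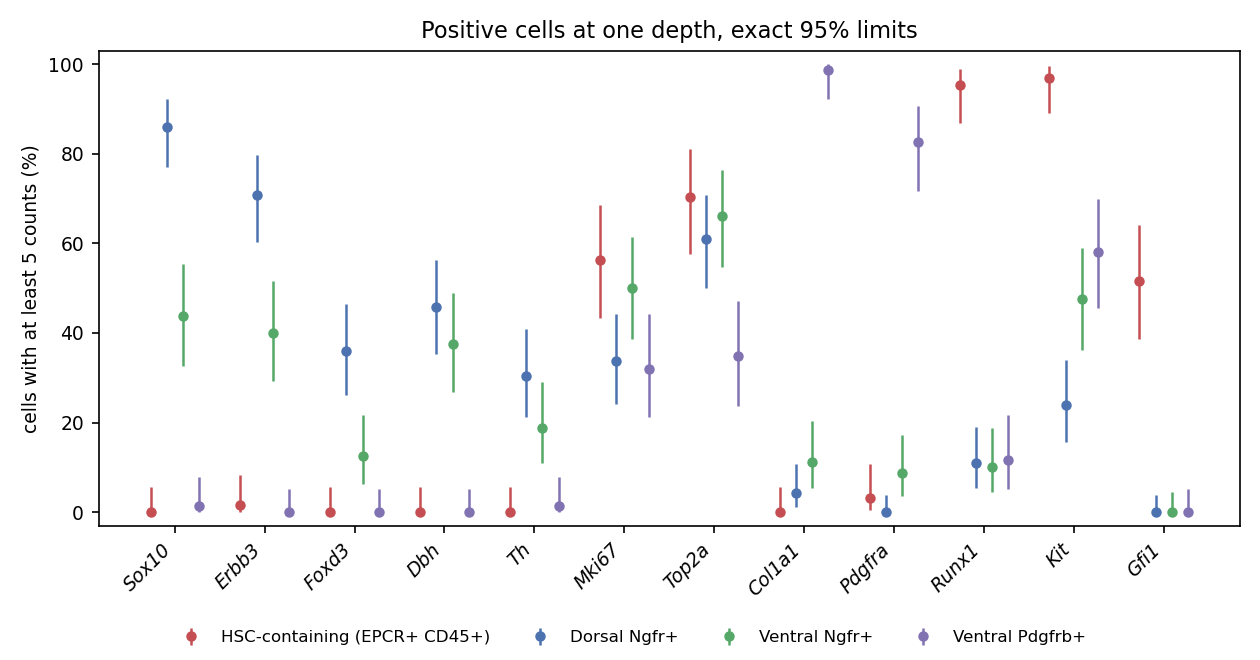
Share of cells with at least 5 counts of each gene in each sorted group, thinned to 1 depth, with 95% limits.

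Sox10 and Dbh were found together in 36 of 92 Dorsal and 13 of 80 Ventral cells. Dbh and Foxd3 were each positive in 0 of 69 Mesenchymal cells, where 3 cells would be 4.35% and the exact upper limit is 5.2%, and in 0 of 64 HSC cells, where they are 4.69% and 5.6%, and Erbb3 in 0 of 69 and 1 of 64. The background was higher within the Ngfr+ pools: macrophage-like cells of cluster 6 were positive for Dbh in 1 of 15 thinned cells (6.7%) and 10 of 17 unthinned cells (58.8%).

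In HSC, Kit was positive in 96.9% of thinned cells, Runx1 in 95.3% (86.9 to 99.0), Ptprc in 92.2%, Procr in 82.8%, Top2a in 70.3%, Mki67 in 56.2%, Gfi1 in 51.6% (38.7 to 64.2; 60% unthinned) and the embryonic globin Hbb-y in 7.8%. Gfi1 was positive in 0 of 92 Dorsal and 0 of 80 Ventral cells, where 3 cells would be 3.26% and 3.75% and the exact upper limits are 3.9% and 4.5%. In Mesenchymal, Col1a1 was positive in 98.6%, Pdgfra in 82.6%, Pdgfrb in 76.8%, Kit in 58%, Acta2 in 44.9% (62.5% unthinned), Top2a in 34.8% and Mki67 in 31.9%.

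Dorsal and Ventral cells were clustered together into 6 clusters, the number of subpopulations the study describes. Cluster 1, 67 cells defined by genes such as Postn, Moxd1, Ednrb and Megf10, carried Schwann cell precursor and neural crest markers and held 53 Dorsal cells (57%, 46.3 to 67.2) and 14 Ventral cells (15.7%, 8.9 to 25). Cluster 2, 27 cells defined by Cd24a, Cdh11, Unc5c, Meis2 and Wt1, was not assigned to a cell type: Wt1, a marker of the mesonephric and coelomic epithelium and gonad set, was the only set marker among its top 10 genes, and 2 sclerotome markers were among its top 50. It held 2 Dorsal cells (2.2%) and 25 Ventral cells (28.1%, 19.1 to 38.6), among them the deepest Ventral cell, and cannot be told from a feature of the Ventral library. Cluster 3 (Igfbp3, Tlx2, Thbd) held 9 Dorsal and 17 Ventral cells, cluster 4 (Tubb3, Nefm, Isl1, Dbh) 12 and 14, and cluster 5 (Agtr2, Dbh, Tubb3, Chgb) 10 and 9; clusters 4 and 5 carried sympathetic neuroblast markers. Cluster 6, defined by C1qb, Csf1r, Apoe and Mrc1, carried macrophage markers and held 7 Dorsal cells (7.5%) and 10 Ventral cells (11.2%). When genes that differed 2-fold between the pools were left out, cluster 1 held 58.1% of Dorsal and 19.1% of Ventral cells, cluster 2 1.1% and 15.7%, clusters 3 and 4 together 10.8% and 29.2%, cluster 5 21.5% and 12.4%, and cluster 6 the same cells. Each share is that of the single cluster with the largest overlap, which for cluster 2 shared 15 of its 27 cells.

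**Figure D4:**
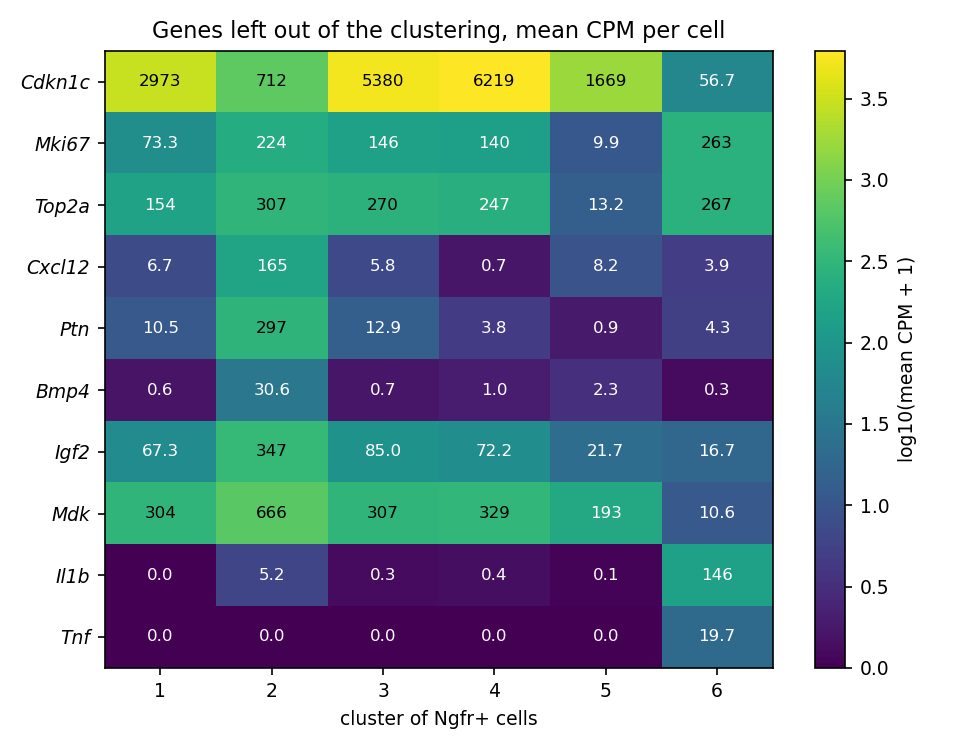
Mean CPM per cell, in each cluster of Ngfr+ cells, of genes left out of the clustering.

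Genes kept out of the clustering differed across its clusters. Mean CPM per cell of Cdkn1c was 6219 in cluster 4, 5380 in cluster 3, 2973 in cluster 1, 1669 in cluster 5, 711.7 in cluster 2 and 56.7 in cluster 6. Mki67 was lowest in the neuroblast-like cluster 5, at 9.9 CPM with 1 of 18 thinned cells positive, against 140 in cluster 4, 146 in cluster 3, 73.3 in cluster 1, 224 in cluster 2 and 263 in cluster 6. Cxcl12 stood at 165 CPM in cluster 2 and at 0.7 to 8.2 CPM elsewhere, Ptn at 297 against 0.9 to 12.9 CPM, and Igf2 at 347 against 16.7 to 85 CPM. Il1b stood at 146 CPM in cluster 6 and at most 5.2 CPM in any other cluster. Kit was positive in 20 of 26 thinned cells of cluster 4 (76.9%).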

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

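A group of 43 entries without a gene symbol, which no comparison of the report uses, held counts in every sorted group: 706826 in HSC, 635505 in Dorsal, 664982 in Ventral and 552786 in Mesenchymal. They are listed here because they are counts outside the genes analysed; their size was compared with no control. In the deposited log2 values these entries are scaled by a second size factor of the cell, unlike the other entries. They took a median of 0.717% of a cell's counts in HSC, 0.549% in Dorsal, 0.571% in Ventral and 0.783% in Mesenchymal, and the median cell held 134.5, 177.1, 170.7 and 123.0 gene counts per count of these entries. What they are is not stated, and no explanation was tested.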

How the results depend on the processing

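Without the deepest Ventral cell, that cell and the wells that share an index with it, Dock10 and Cep97, cluster 2 or cluster 6 are alternatives chosen after seeing the data; the others were fixed beforehand. The 24 genes the rule picked in each comparison kept their direction under the 11 alternatives that the rule does not already require and that change a fold, with 255, 264 and 264 of 264 values at least 2-fold. Over all 16 alternatives the size of the fold moved beyond its counting limits in 330, 358 and 358 of 384 values. Among the Dorsal against Ventral folds printed in the report, those of Nr2f1, Eif2s3y and Th changed sign without the deepest Ventral cell. Ventral against Mesenchymal, these list counts kept within 1.5 times: 9 to 12 for 10 sympathoadrenal factors, 11 to 16 for 15 pan-neuronal genes, 9 to 12 for 10 ligands, 18 to 23 for 19 matrix genes and 13 to 17 for 17 smooth muscle genes. In HSC the haematopoietic factors kept within 17 to 22 and the matrix genes within 12 to 20. Of all list counts 174 of 816 moved for Dorsal against Ventral, 97 of 800 for Ventral against Mesenchymal and 79 of 800 for HSC. The thresholds on counts, genes and mitochondrial share removed 0 cells, so that alternative is void. Depth limits the shares of positive cells and weights deep cells.

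For Dorsal against Ventral the following counts moved. In odd-index cells 6 neural crest genes were higher and 18 cell cycle genes lower; in even-index cells 4 catecholamine genes were within 2-fold and 3 cell cycle genes lower. Without the deepest Ventral cell 7 neural crest genes were higher and 17 cell cycle genes lower (18 also without the wells that share an index with it), and without the 5% deepest cells 4 cell cycle genes were lower. Without cluster 2 the counts were 6 neural crest genes, 18 cell cycle genes and 3 mesenchymal factors, and with the deposited log2 values 3 niche ligands and 4 mesenchymal factors were lower. In HSC 4 Hox genes were lower with a pseudocount of 5 CPM and 8 with the deposited log2 values. For all of these the cause was not tested.

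Shares of positive cells moved with the count limit. With at least 1 count they were 54.3% and 31.2% (Th, Dorsal and Ventral), 89.1% and 78.8% (Dbh), 96.7% and 71.2% (Sox10), 47.8% and 80% (Mki67), 76.1% and 88.8% (Top2a) and 65.6% (Gfi1, HSC). With at least 10 counts they were 32.6% (Dbh, Dorsal), 47.8% and 52.5% (Top2a). Unthinned they were 86% and 59.6% (Dbh) and 94.6% (Sox10, Dorsal). Dbh in Ventral was 50% in odd-index and 25% in even-index cells, and Runx1 in HSC 100% in even-index cells; the cause was not tested.

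Cluster shares moved most under Leiden clustering (adjusted Rand index 0.51): 35.5% of Dorsal and 6.7% of Ventral cells in cluster 1, and 20.4%, 2.2% and 22.6% of Dorsal cells in clusters 3, 4 and 5. The single cluster that overlapped cluster 2 most held 15.7% of Ventral cells with 7 clusters and 15% in thinned cells. Without genes that differ between the pools it held 15.7% and shared 15 of the 27 cluster 2 cells. Where the remaining cluster 2 cells fell was not followed, so a lower share may be a split of cluster 2. Without genes that differ between the pools clusters 3 and 4 each matched the same 29.2% of Ventral cells and cluster 5 held 21.5% of Dorsal cells. With 5 clusters, clusters 4 and 5 matched the same 23.7% of Dorsal and 25.8% of Ventral cells; Dorsal shares of both were 22.6% with the held-out lists and 22.8% in thinned cells. The cause was not tested.

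No paired analysis was possible because the labels name no animal or litter that 2 groups share.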

Other observations

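Within the Ngfr+ pools, the Hox genes of groups 10 to 12, which mark the posterior body axis, were set apart from the others after the values were seen. Of 6 such genes 5 were at least 2-fold higher in Ventral and 0 in Dorsal, with a median log2 fold of -2.05, and over the cells of clusters 1, 3, 4 and 5 the median was -1.38 with 4 higher in Ventral. In these clusters the odd-index cells gave -0.89 to 0.42, with 0 genes at least 2-fold different, and the even-index cells -3.22 to 0.03, and Hoxa11 and Hoxd11 were at 5 or more counts in 3 Ventral cells each. The 25 genes of groups 1 to 9 had medians of 0.49 and 0.31.

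Genes of the Y chromosome were at 5 or more counts in 51 of 64 HSC, 40 of 92 Dorsal, 32 of 80 Ventral and 19 of 69 Mesenchymal thinned cells. Igf1 had a mean of 325.9 CPM per cell in cluster 6, 132.8 in cluster 2 and 73.1 in cluster 3.

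The tests of the mesenchymal and cell cycle patterns were chosen after the result was seen, and those of the macrophage pattern before.

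The 16 mesenchymal transcription factors and niche ligands that were at least 2-fold higher in Ventral Ngfr+ cells had a median log2 fold of -3.66. Without the deepest Ventral cell it was -2.1, and 15 of the 16 stayed at least 2-fold, which argues against that cell as the whole cause; without the wells that share an index with it as well the median was -1.96 with 14 of the 16. Over the crest-derived clusters 1, 3, 4 and 5 it was -0.18, with 12 of the 16 below 0. This argues against those clusters as the source of a fold of that size, although Foxc2 (-1.23) and Ptn (-1.7) stayed at least 2-fold. The 1 CPM added before the ratio pulls folds of genes near 0 CPM towards 0. A difference at low levels within those clusters is therefore not excluded. Without the cells of cluster 2, which include the deepest Ventral cell, the median was -0.61 and 5 stayed at least 2-fold. Cells of cluster 2 could thus carry much of the pattern, and this test leaves it open. Of the 5, Il1b (-5.05), Vcam1 (-2.45) and Tnf (-1.62) stood at -0.49, 0.65 and -0.05 over clusters 1, 3, 4 and 5. Those clusters leave out the macrophage-like cluster 6. Of thinned cluster 2 cells 58.3% were positive for Ngfr, 16.7% for Pdgfrb and 37.5% for Col1a1, against 98.6% of Mesenchymal cells for Col1a1; what cluster 2 is was not settled.

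The 11 cell cycle genes that were at least 2-fold lower in Dorsal had a median log2 fold of -1.47. Both pools were also weighted to the same makeup of the clusters with at least 5 cells of each pool, without cluster 2. The weighted median was -1.29, with all 11 at least 2-fold lower in Dorsal. Unweighted and without the cells of cluster 2, the genes stood between -1.55 (Mki67) and -2.35 (Ccnb2). This argues against the makeup of the weighted clusters as the whole cause, but makeup could carry a part. The 11 genes were picked from these same pools, and deep cells still weighed more within each cluster and pool. The weighting therefore does not address a few deep cells. With every cell weighted equally the median was -1.18, but without the 5% deepest cells it was -0.91. In odd-index and even-index cells it was -1.82 and -0.74, so the part of a few deep cells stays open. This verdict was set after the -0.91 was seen. In cluster 1 alone the median was 0.18, and over clusters 1, 3, 4 and 5 it was -2.03.

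Macrophage markers were found at low counts in Ngfr+ cells outside cluster 6, which held 2.41% of marker counts in Dorsal and 3.11% in Ventral. Wells that shared more index exposure with cluster 6 cells held more: 60.27 against 24.27 counts per cell in Dorsal, a ratio of 2.48, and 59.46 against 23.25 in Ventral, a ratio of 2.56. For the summed markers, the lower ratio of 2.48 is what cross-talk between indices predicts and argues against free RNA as the whole source. It does not settle the source of Fcer1g, whose share outside cluster 6 was far above that of C1qb. Genes held almost wholly by 1 or 2 cells showed the same in wells sharing an index, with ratios of 25.54 in HSC and 2.13 in Ventral, but in Ventral 11461 of their counts outside the source cells lay in wells sharing no index and 5854 in wells sharing one, so where most of those came from is open. No biological explanation was tested, and swaps within a pool hardly alter its summed counts.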
